A study of Mus musculus with 3 samples.

How the data were processed

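Total RNA-seq libraries depleted of ribosomal RNA were made from the chromatin fraction of mouse bone marrow-derived macrophages (BMDM), per the labels. The labels describe 1 group of 3 biological replicates and give their replicate numbers, separate biosamples and a shared donor identifier. The p-values over libraries therefore measure the spread between these samples. The RNA put into the libraries was 1 µg for replicate 1, 250 ng for replicate 2 and 500 ng for replicate 3, per the labels, so input amount and replicate cannot be told apart.

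Each library had a gene table and 2 transcript tables. The gene table and the first transcript table hold expected counts and TPM (transcript abundance corrected for effective length and scaled to a fixed sum), per the file headers, and their column layout is the one RSEM writes. The second transcript table holds estimated counts and TPM, per the file headers, and its layout is the one kallisto writes. The deposited text file beside each sample gives the mm10 assembly and annotation release M21 for all of them. It derives the first 2 tables from transcriptome alignments and the second transcript table directly from the reads. The aligner, the versions of the tools, and whether the counting used strand are not given in the sources used here. Reads from overlapping genes on opposite strands, from paralogs and from pseudogenes may therefore be shared, and values of such genes are uncertain. No library was pooled, per the labels.

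All 55536 genes of release M21 were matched by identifier, and gene names, types and mm10 coordinates were taken from that annotation. The gene tables also hold 96 ERCC spike-in rows, a phiX row and 26248 numbered rows that name no gene. These rows were left out of library sizes and tests, and their counts were 1.04%, 0.425% and 0.401% of the total for phiX in replicates 1, 2 and 3, 0 for the ERCC rows and 23 to 33 counts for the numbered rows. Total expected counts were 12532722, 18395358 and 18237730. A gene with 0 counts could have had up to 3 counts, which is 0.242, 0.164 and 0.165 CPM (counts scaled to a fixed sum of reads, with no length correction) in the 3 libraries. For the ratios of list medians, members below the TPM of 3 counts summed over the group were raised to that value. Reads were not marked as separate molecules in the sources used here, so these floors cover counting error only. Chi-square per degree of freedom between pairs of libraries was 40.2 to 76.0 over genes, so no library was a copy of another.

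No second group was analysed here, so levels were compared with a fixed floor, between gene lists and between libraries. An intercept-only limma (3.58.1) model of log2(TPM + 0.1) was tested one-sided against 1 TPM for the 24180 genes with a nonzero value, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values on this log2 scale understate differences of genes near 0.1 TPM. In simulated data, 0% of 50 genes at 1 TPM, 72% of 50 genes at 2 TPM and 100% of 50 genes at 4 TPM were called, over 22356 genes. The simulation gave every gene a biological coefficient of variation of 0.3 and used only effective lengths of at least 100 bases. Genes with a larger spread can miss the threshold at such levels, as Fosb did with a mean of 4.04 TPM. The 20 gene lists, which hold 324 distinct annotated gene identifiers, were fixed before the data were examined. The median of each list was compared with that of the other genes (protein-coding genes with mean TPM over 0.1 and all list members) by a two-sided permutation test of 100000 random sets, adjusted over the 20 lists. The 10 pairs of lists were compared by permuting membership 100000 times, or by exact enumeration where a list had fewer than 10 members, and adjusted over the 10 pairs. In each set of 40 simulated lists of 20 genes tested among 12921 genes, 0, 9 and 31 passed at shifts of 0, 1 and 2 on the log2 scale. Genes are not independent replicates, and these tests describe the lists in these libraries.

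The spread between libraries was estimated with edgeR (4.0.16) from expected counts rounded to whole numbers, with TMM scaling and filterByExpr, which kept 14140 genes. In simulated counts of 14155 genes with a biological coefficient of variation of 0.3, the estimate was 0.293. The shift of a list in a library was the median log2 difference in TMM-scaled CPM from the mean of the other libraries, relative to all protein-coding genes, and its percentile was taken among 10000 random lists matched on mean expression in 20 bins. This measure was chosen after seeing the data. Transcript classes were taken from the annotated transcript type. R 4.3.3, DESeq2 1.42.0, python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

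The named genes were chosen by a rule fixed before the data were examined. It took the 10 nuclear protein-coding genes and the 10 other genes with the highest mean TPM, the 3 highest members of each list, any marker of other cells above the floor, a fixed set of macrophage response genes, and the 10 genes with the largest SD of log2 CPM among those with a mean expected count of at least 100. A list member named outside this rule is marked in the text as chosen after its value was seen. Alternatives covered the pseudocount (1 or 0.01), the floor (0.5 or 5 TPM), a filter of 10 expected counts in 2 libraries, rescaled TPM, the second transcript table summed per gene, CPM in place of TPM, other backgrounds, other scalings and dispersions (DESeq2), and each replicate left out. TPM rescaled over genes with an effective length of at least 100 bases was added after seeing the data.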

Results

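Chromatin-associated RNA was measured in bone marrow-derived macrophages of C57BL/6J mice by ribosomal RNA-depleted total RNA-seq. The cells were exposed to 100 ng/ml lipid A, the part of lipopolysaccharide that activates TLR4, for 12 h, kept without it for 12 h, and stimulated again with 100 ng/ml for 30 min, per the labels. The chromatin fraction is enriched for RNA still attached to its template, so it reads ongoing transcription more closely than whole-cell RNA does. The data comprised 1 group with 3 biological replicates from 1 donor identifier. Total expected counts were 12532722 in replicate 1, 18395358 in replicate 2 and 18237730 in replicate 3, and 20988 to 21683 genes had a nonzero TPM per library. The series addressed the state of the chromatin RNA after a second lipid A exposure. No unexposed or singly exposed cells were analysed here, so no level below can be read as a response to lipid A.

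By mean TPM, the highest protein-coding chromatin RNA was that of Lilrb4a, although in replicate 2 it had 1240 TPM and Mx1 2006 TPM. Lilrb4a, an inhibitory immunoglobulin-like receptor on chromosome 10, had 2185 ± 842 TPM (SD, n = 3), and its neighbour Lilr4b had 1456 ± 582 TPM (SD, n = 3). Mx1, an interferon-induced gene, had 1880 ± 586 TPM, the class I histocompatibility gene H2-K1 had 1695 ± 310 TPM, and the transcription factor gene Zeb2 had 1305 ± 279 TPM (SD, n = 3 each). Rsrp1, Fyb, Tcirg1, Ikbke and Fth1 completed the 10 highest, with 1296, 1173, 1164, 1154 and 1075 TPM. The order differed in the second transcript table, where Ikbke had 1840, H2-K1 1159 and Fth1 724 TPM. Gpnmb, outside these 10, had 1326 TPM there. Lilrb4a and Lilr4b are close paralogs and H2-K1 belongs to a family of similar genes, so the split of reads between copies is uncertain. Transcripts annotated as retaining an intron took 99.9% of the expected counts of Lilrb4a and 94.3% of those of Lilr4b. Among these 10 genes the share was lowest for Mx1, at 3.14%. Lilrb4a was 10.87 log2 units above 1 TPM (SE 0.30, limma adjusted p = 1.51e-06) in 3 of 3 libraries. As the gene was named for its high TPM, passing this floor was given in advance.

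Several noncoding RNAs had higher TPM than any coding gene in the gene table. The small nucleolar RNA gene Gm22988 (mm10 chromosome 11, 69669635 to 69669778, minus strand) had 71447 ± 16344 TPM, and Rmrp, the RNA of the RNase MRP complex, had 69713 ± 26737 TPM for its ribozyme entry. An overlapping Rmrp entry on the same strand, typed as long intergenic noncoding, had 2235, 21124 and 10567 TPM in replicates 1, 2 and 3. The split of reads between these entries is uncertain. In the second transcript table the ribozyme entry had 25646 TPM and the other entry 5490 TPM. Gm26917, annotated as a long intergenic noncoding RNA on chromosome 17, had 54551 ± 16963 TPM, and CT010467.1, typed as a ribosomal RNA gene beside it, had 14074 ± 9149 TPM. The genes of that ribosomal RNA locus took 10.5%, 20.8% and 18.2% of expected counts in replicates 1, 2 and 3. Other small RNAs in the 10 highest were Gm26447 (49479 TPM), Snord15b (30405 TPM), Gm25776 (15342 TPM), Rn7sk (14840 TPM) and Gm25835 (14168 TPM). The TPM of the shortest small RNAs is uncertain, since the mean effective length was 3.27 bases for Gm22988 and 1.24 bases for Gm26447. In the second transcript table these 2 had 6348 and 2232 TPM. Snord15b, Gm25776, Gm25835 and Rn7sk had 2967, 1542, 1532 and 7129 TPM there. Malat1, a nuclear-retained RNA, had 28211 ± 4169 TPM, and Neat1, the RNA scaffold of paraspeckles, had 2531 ± 314 TPM (SD, n = 3).

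Of 24180 genes tested, 12220 were above 1 TPM (limma, adjusted p under 0.05), of which 9239 were protein-coding, 290 long intergenic noncoding and 543 antisense genes. The count was 19620 when the second transcript table was summed per gene, and 7384 with a floor of 5 TPM.

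Several inflammatory cytokine genes had abundant chromatin RNA while others were near 0. Tnf had 484 ± 177 TPM, Ccl5 433 ± 148 TPM, Cxcl2 409 ± 273 TPM, Cxcl10 296 ± 162 TPM and Il1b 295 ± 155 TPM (SD, n = 3 each). Il10, an anti-inflammatory cytokine, had 25.2 ± 20.4 TPM, and Nos2, the inducible nitric oxide synthase, had 5.16 ± 2.27 TPM. Il6 had 3.25, 0.61 and 4.55 TPM in replicates 1, 2 and 3 (adjusted p = 0.13, limma), and Il12b had 0.56, 0.08 and 1.75 TPM (adjusted p = 1). Without replicate 2, Il6 passed the test at 1.84 log2 units above the floor. Of the 25 inflammatory cytokine and enzyme genes, 17 were above 1 TPM, and 17 when adjusted over the list alone. Among the 8 that were not, Cxcl3, Csf2, Csf3 and Lif had means of 0.137, 0.04, 0.0767 and 0.0733 TPM and were singled out after their values were seen.

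The list of inflammatory genes had a median of 25.7 TPM and stood 1.73 log2 units above other genes (SD 1.35 over 3 libraries, permutation p = 0.0171, adjusted p = 0.0245). Its difference was positive in 3 of 3 libraries, at 1.87, 0.21 and 2.88, and without replicate 3 it was 1.17 and missed the threshold. Tnf, at chromosome 17 of mm10, was 8.70 log2 units above 1 TPM (SE 0.25, limma adjusted p = 1.72e-06).

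Negative regulators of TLR and NF-kB signalling were among the higher lists. The list name is a label for a membership set beforehand. Whether each member, Nfkbiz and Birc3 included, inhibits signalling in these cells was not tested, so the list level is not a measure of inhibition. Tnip3, an A20-binding inhibitor, had 660 ± 243 TPM, Tnfaip3, which encodes A20, had 450 ± 203 TPM, and Birc3, a ubiquitin ligase of the pathway, had 362 ± 115 TPM (SD, n = 3 each). Nfkbia, which encodes the inhibitor IkBa, had 358 ± 152 TPM, Nfkbiz 320 ± 172 TPM, and Irak3, an inhibitory member of the IRAK family, 26.4 ± 4.96 TPM. The test called 20 of 22 members above 1 TPM, and 20 adjusted over the list alone. The 2 that did not pass, named after their values were seen, were Cish (1.54 TPM) and Sigirr (0.393 TPM). The list median was 62.5 TPM, which was 3.21 log2 units above other genes in the mean over libraries (SD 0.47, permutation p = 7e-05, adjusted p = 0.000175) and above them in 3 of 3 libraries. The cytokine list lay 1.47 log2 units lower, at -1.47 (SD 1.09 over 3 libraries), and this difference did not pass the permutation test (p = 0.198, adjusted p = 0.248). Over members with a mean expected count of at least 10 it turned to 0.49, also not past the threshold.

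Immediate-early genes, whose transcription starts without new protein synthesis, were also abundant. Zfp36, which encodes an mRNA-destabilising protein, had 279 ± 101 TPM, Klf6 262 ± 103 TPM and the phosphatase gene Dusp2 191 ± 86.7 TPM (SD, n = 3 each). Dusp1 had 191 ± 71.5 TPM, Egr1 148 ± 84.5 TPM and Fos 67.0 ± 45.0 TPM. Of 22 members, 20 were above 1 TPM, and 20 adjusted over the list alone. Fosb had 0.5, 0.84 and 10.8 TPM in replicates 1, 2 and 3 and did not pass (limma adjusted p = 0.392). The list was 2.86 log2 units above other genes (SD 0.70 over libraries, permutation p = 0.00033, adjusted p = 0.00066). Its difference from the cytokine list did not pass the test (1.13 log2 units, SD 0.66, permutation p = 0.55, adjusted p = 0.611), and over members with a mean expected count of at least 10 it turned to -0.84.

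Interferon-stimulated genes were the highest of the coding gene lists. Mx1 led the list at 1880 TPM, followed by Rsad2, the antiviral enzyme viperin, with 669 ± 309 TPM and Stat2 with 570 ± 96.7 TPM (SD, n = 3 each). Ifit1 had 79.3 ± 21.9 TPM. Ifnb1, the gene of interferon-beta itself, had 1.73, 0.78 and 0.93 TPM and was the 1 of 24 members that was not above 1 TPM (limma adjusted p = 0.675). The other 23 were called, and 23 adjusted over the list alone. The median was 147 TPM, 4.50 log2 units above other genes (SD 0.33 over libraries, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 3.33e-05), in 3 of 3 libraries. Immediate-early genes lay below this list (log2 difference -1.64, SD 0.78, permutation p = 0.00375, adjusted p = 0.00536), as did the cytokine list (-2.77, SD 1.34, permutation p = 0.00022, adjusted p = 0.00044), both in 3 of 3 libraries. Over members with a mean expected count of at least 10, the cytokine difference was -0.97 and did not pass.

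**Figure D1:**
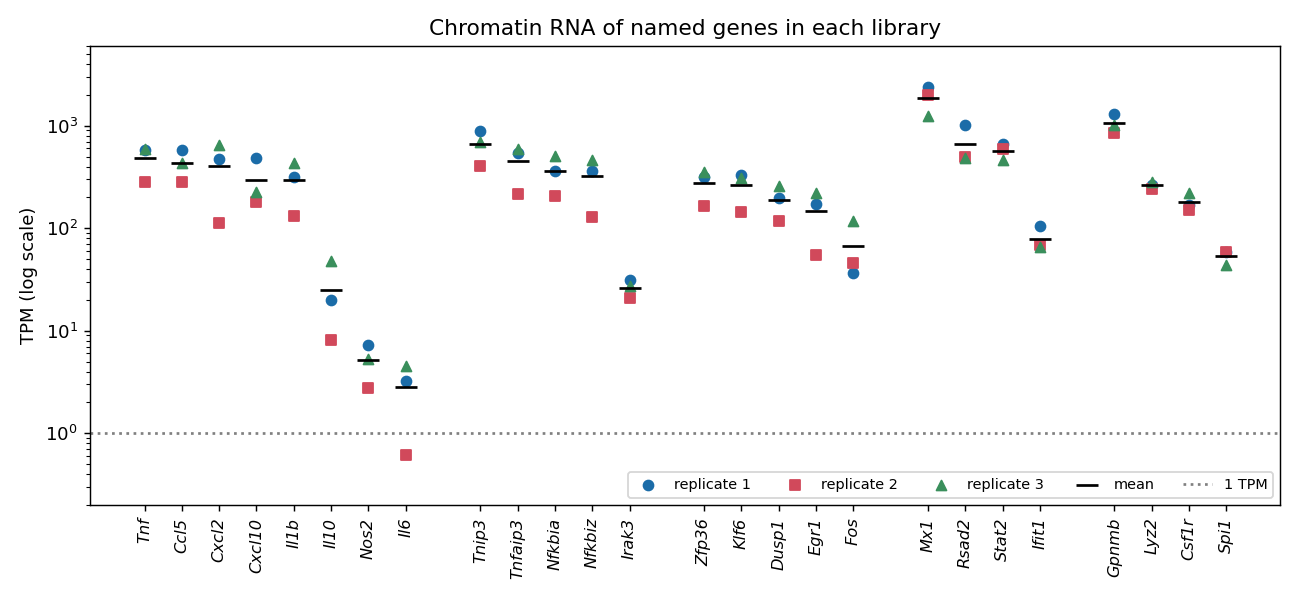
TPM on a log axis for genes of 5 preset lists, from left to right cytokines, negative regulators, immediate-early, interferon-stimulated and macrophage identity genes. Points are the 3 libraries, the bars are means and the dotted line is 1 TPM. Tnf averaged 484 TPM and Il6 had 0.61 TPM in replicate 2.

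Antimicrobial and scavenger effector genes were split between high and near-absent members. Acod1, which makes itaconate, had 839 ± 394 TPM, Sod2, the mitochondrial superoxide dismutase, had 733 ± 287 TPM and the C-type lectin gene Clec4e had 446 ± 248 TPM (SD, n = 3 each). Saa3 had 169 ± 30.5 TPM and the scavenger receptor gene Marco 26.3 ± 5.94 TPM. Lcn2, an iron-sequestering protein gene, had 1.93 ± 0.817 TPM and missed the threshold (limma adjusted p = 0.0558), and without replicate 2 it passed at 1.14 log2 units above the floor. Camp, Slpi, Hp and Ltf, named after their values were seen, had means of 0.0867, 0.0367, 0.113 and 0.0733 TPM. The test called 12 of 17 members, and 13 adjusted over the list alone. The list stood 2.01 log2 units above other genes (SD 0.26, permutation p = 0.0221, adjusted p = 0.0294), in 3 of 3 libraries, and with CPM in place of TPM the difference was 1.85 and missed the threshold. The cytokine minus effector difference did not pass the test (-0.28, SD 1.09, permutation p = 1, adjusted p = 1) and turned to 0.05 with CPM. All 25 TLR4 signalling components were above 1 TPM, and 25 adjusted over the list alone. The highest were Tbk1 (176 ± 25.2 TPM), Irak2 (102 ± 25.9 TPM) and Chuk (92.5 ± 6.53 TPM), and the list was 2.42 log2 units above other genes (SD 0.29, permutation p = 0.00146, adjusted p = 0.00243).

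Macrophage identity genes were abundant, and in the gene table most markers of other cell types were near 0. Gpnmb, a lysosomal and melanosomal glycoprotein gene, had 1054 ± 226 TPM, the cathepsin gene Ctsb 423 ± 75.9 TPM and Adgre1, which encodes F4/80, 345 ± 27.3 TPM (SD, n = 3 each). Lyz2 had 262 ± 20.1 TPM, the receptor gene Csf1r 178 ± 36.0 TPM and the lineage factor gene Spi1 53.7 ± 8.69 TPM. Of 25 members, 22 were above 1 TPM, and 22 adjusted over the list alone. The exceptions, named after their values were seen, were Cebpa, Lyz1 and Cx3cr1, with means of 0.92, 0.19 and 0.0367 TPM. In the second transcript table Cx3cr1 had 3.12 ± 0.516 TPM, and 23 members were called there. The list was 3.10 log2 units above other genes (SD 0.27, permutation p = 0.00011, adjusted p = 0.000244), in 3 of 3 libraries.

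No lymphoid marker of 12, no granulocyte or mast cell marker of 13 and no stromal, endothelial or epithelial marker of 12 was above 1 TPM, with 0 calls also when adjusted over each list alone (limma). The highest means in these lists belonged to genes at or below 0.66 TPM. Kit had 1.33, 0.1 and 0.55 TPM in replicates 1, 2 and 3, and Lck 0.26, 0 and 0.37 TPM. Col3a1 had 0, 0.75 and 0.6 TPM and Col1a1 0, 0.51 and 0.56 TPM. Both collagen genes had reads in replicates 2 and 3 only. Cd8a had 0.113 ± 0.085 TPM. The second transcript table called 2 lymphoid, 1 granulocyte and 1 stromal marker and 3 dendritic and 3 erythroid markers. Those not called in the gene table, named after their values were seen, were Cd3d, Cd8a, Mpo, Col1a1, Siglech, Zbtb46 and Itga2b, with means there of 15.4, 2.63, 1.74, 1.80, 2.01, 1.90 and 4.40 TPM. Cd3d had 0.0167 TPM in the gene table. Of 8 dendritic cell markers only Batf3 was called in the gene table, at 4.31 ± 2.52 TPM (1 adjusted over the list alone). Clec9a and Zbtb46 had 0.98 and 0.837 TPM. Of 10 erythroid and megakaryocyte markers Pf4 (3.32 ± 0.976 TPM) and Gp9 (2.89 ± 1.43 TPM) were called, and 2 adjusted over the list alone. Itga2b had 1.55 ± 0.85 TPM and passed without replicate 2, at 0.89 log2 units above the floor.

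The log2 differences from other genes were -5.82 for lymphoid, -6.01 for granulocyte and mast cell, -4.84 for dendritic, -5.44 for erythroid and megakaryocyte and -5.62 for stromal, endothelial and epithelial markers, each with permutation p = 1e-05, the smallest possible, and adjusted p = 3.33e-05. These values rest on the pseudocount, since many members had few or no reads. They also rest on the filter, since other genes entered only with a mean TPM over 0.1 and list members at any level. The list medians lay at percentile 0 of that background, and at 2.89 for dendritic markers, so small p-values were largely fixed in advance. With each member that had less than the TPM of 3 counts over the group raised to that value, the median of the macrophage list, 57.4 TPM, was 784-fold higher than that of lymphoid, 414-fold higher than granulocyte and mast cell, 355-fold higher than dendritic, 222-fold higher than erythroid and megakaryocyte, and 812-fold higher than stromal, endothelial and epithelial markers. These are ratios of medians and not bounds, since some of the medians rest on genes with reads. In replicate 3 the macrophage and dendritic medians were 43.7 and 0.365 TPM. With no value raised, the second transcript table gave ratios of 608, 1635, 69.1, 1375 and 280 for the lists in that order. The list-against-list tests gave adjusted p = 0.0001 for lymphoid, granulocyte, erythroid and stromal markers by permutation and adjusted p = 0.000816 for dendritic markers by exact enumeration, with the macrophage list higher in 3 of 3 libraries. Against a background of all protein-coding genes without a filter, the differences of these 5 lists did not pass the test. The dendritic difference also did not pass in the second transcript table, at -2.43.

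**Figure D2:**
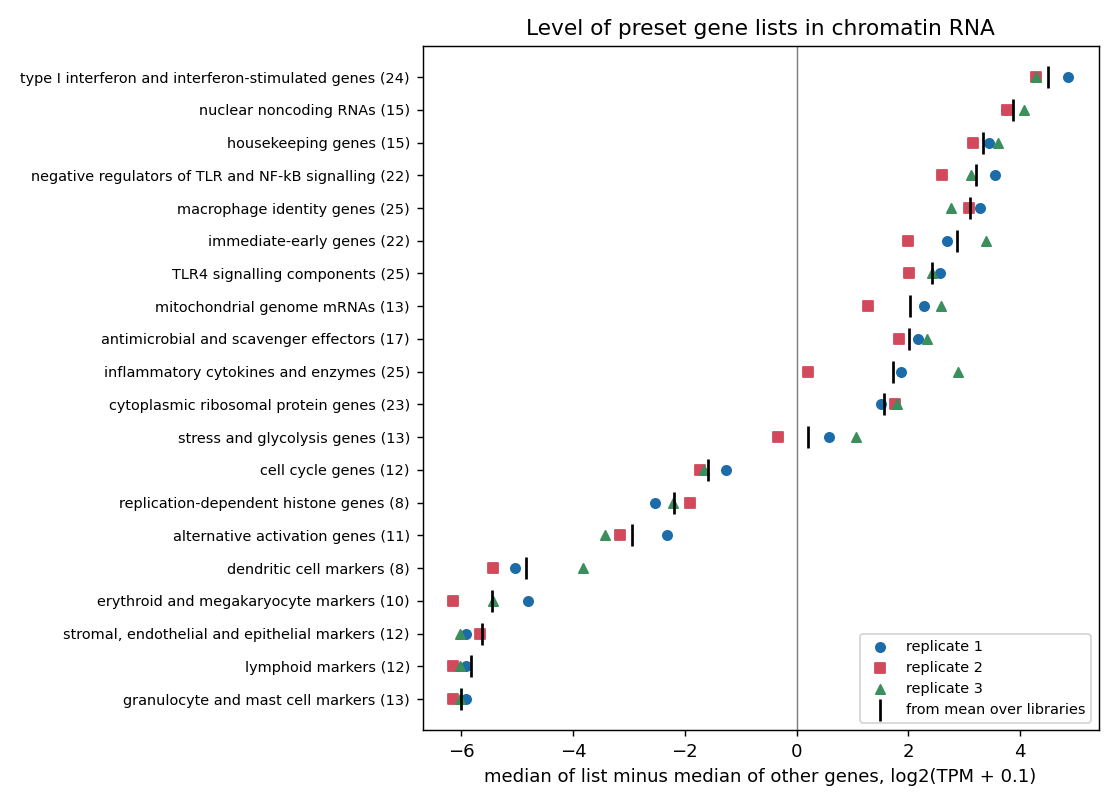
Median of each preset list minus the median of other genes, in log2(TPM + 0.1), with the number of members in parentheses. Points are the 3 libraries and black bars use the mean over libraries. Interferon-stimulated genes stood at 4.50 and granulocyte and mast cell markers at -6.01.

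Alternative activation genes were low as a list, with a median of 0.767 TPM, but held both extremes. Vegfa had 104 ± 35.5 TPM, Il4ra, the interleukin-4 receptor alpha chain gene, 59.7 ± 22.8 TPM and the lectin gene Clec10a 4.59 ± 0.139 TPM (SD, n = 3 each). Chil3, Retnla and Mgl2, singled out after their values were seen, had 0 counts in all 3 libraries, which allows up to 0.154, 0.207 and 0.0856 TPM at 3 counts over the group in that table. Retnla had 0.714 ± 0.302 TPM and Mgl2 0.109 TPM in the second transcript table, so these limits cover counting error only. Of 11 members 4 were called, and 4 adjusted over the list alone. The list lay -2.95 log2 units from other genes (SD 0.57, permutation p = 0.0084, adjusted p = 0.0129), in 3 of 3 libraries. In the second transcript table the difference was -1.65 and missed the threshold. Against all protein-coding genes without a filter it was 0.43, in the other direction and not past the threshold.

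The difference of stress and glycolysis genes from other genes did not pass the test (0.21 log2 units, SD 0.72, permutation p = 0.822, adjusted p = 0.822), with 10 of 13 above 1 TPM and 11 adjusted over the list alone. Txnrd1, Pfkfb3 and Hif1a were the highest, with 131 ± 70.1, 58.9 ± 16.5 and 19.9 ± 3.73 TPM. That of cell cycle genes did not pass either (-1.58, SD 0.26, permutation p = 0.106, adjusted p = 0.111), with 7 of 12 called and 7 adjusted over the list alone. Mki67, Pcna and Top2a had 32.4 ± 19.1, 23.0 ± 1.10 and 5.72 ± 1.33 TPM. Replication-dependent histone genes stood at -2.19 (SD 0.32, permutation p = 0.0635, adjusted p = 0.0706), and without replicate 2 they passed, at -2.50. Against all protein-coding genes without a filter, the cell cycle and histone differences both turned positive. The cell cycle difference also turned positive in the second transcript table. Of 8 histone genes 2 were called, Hist1h4i (5.62 ± 1.52 TPM) and Hist1h2bc (2.16 ± 1.26 TPM), and 1 adjusted over the list alone. Leaving out any 1 replicate ended the call of Hist1h2bc and left 1 histone gene. Hist1h1c had 1.98 ± 1.61 TPM and was not called.

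Nuclear noncoding RNAs were 3.88 log2 units above other genes (SD 0.18, permutation p = 4e-05, adjusted p = 0.000114), with 13 of 15 called and 13 adjusted over the list alone, led by Rmrp, Malat1 and Rn7sk. Both overlapping entries of Rmrp count among the 15. Housekeeping genes were 3.34 units above (SD 0.23, permutation p = 0.00057, adjusted p = 0.00104), with 15 of 15 called and 15 adjusted over the list alone. Actb had 523 ± 46.1 TPM, Ftl1 376 ± 66.0 TPM and Gapdh 18.5 ± 3.87 TPM. Ribosomal protein genes were 1.56 units above (SD 0.15, permutation p = 0.0371, adjusted p = 0.0463), with 23 of 23 called and 23 adjusted over the list alone. Rpl10, Rps9 and Rpl3 had 127 ± 12.3, 93.2 ± 22.4 and 67.8 ± 19.2 TPM. Without replicate 2 the ribosomal protein difference was 1.42 and missed the threshold, and with CPM in place of TPM it was 0.10. These genes have many pseudogene copies that can share their reads.

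Mitochondrial mRNAs were 2.02 units above other genes (SD 0.69, permutation p = 0.042, adjusted p = 0.0494), with 8 of 13 called and 8 adjusted over the list alone. The highest were mt-Co1, mt-Atp8 and mt-Nd6, with 224 ± 78.6, 157 ± 56.1 and 53.9 ± 29.2 TPM. Without replicate 3 the difference was 1.77 and missed the threshold, as it did with CPM (0.14). Several of these values are uncertain, and the genes that follow were chosen after their values were seen. mt-Co2 was listed at 0 in all 3 libraries of the gene table and had a mean of 21.8 TPM in the second transcript table. mt-Atp6 had 0, 0 and 61.7 TPM in replicates 1, 2 and 3 (mean of 39.4 TPM in the second table), mt-Nd3 0, 0 and 26.5 TPM (4.04) and mt-Co3 1.95, 0.03 and 13.6 TPM (29.9), while mt-Nd4l was at 0 in replicate 1. The value of mt-Atp8 rests on a mean effective length of 22.2 bases, and the second table gave it 52.5 TPM.

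The libraries shared most of their profile but differed in the inflammatory genes. Across 24180 genes, which are not independent replicates, Pearson's r of log2(TPM + 0.1) was 0.936 between replicates 1 and 2, 0.941 between 1 and 3, and 0.941 between 2 and 3. The common biological coefficient of variation was 0.219 (edgeR), and 0.173 without replicate 2. Of 14140 genes kept by the filter, 1273 differed over 2-fold between replicates 1 and 2, 603 between 1 and 3 and 997 between 2 and 3. The genes with the largest spread were Fosb, Gm26759, Slc7a11, Cxcl1, Tnfsf9, Gem, Nr4a1, Egr2, Srgn and Dnmt3l-ps1, whose highest library exceeded the lowest 18.9-, 13.7-, 14.2-, 12.0-, 11.0-, 10.4-, 8.61-, 8.33-, 9.04- and 7.62-fold. Cxcl1 had 48.9, 6.64 and 86.3 TPM in replicates 1, 2 and 3, Tnfsf9 had 168, 22.6 and 240 TPM, and the cystine transporter gene Slc7a11 had 8.9, 1.71 and 25.3 TPM.

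Replicate 2 was lower in inflammatory genes as lists. Relative to all protein-coding genes, the cytokine list was shifted by -1.49 log2 units in replicate 2, with 19 of 19 expressed members lower, the immediate-early list by -1.17 (20 of 21), the effector list by -1.12 (12 of 12) and the negative regulators by -0.83 (20 of 21). Each of these medians lay below all of 10000 random lists matched on expression, as did mitochondrial mRNAs at -1.03. The random lists were not matched on co-regulation. Lists of genes that move together can therefore leave their range more easily, and these percentiles describe the libraries only. Macrophage identity genes were shifted by -0.11 (percentile 45.7) and TLR4 components by -0.15 (percentile 21.5). Stress and glycolysis genes were shifted by -0.42 (percentile 0.22), housekeeping genes by -0.30 (percentile 1.61) and histone genes by 1.15 (percentile 99.9). Interferon-stimulated genes were shifted by -0.34 in replicate 2 (22 of 23, percentile 0.76). In replicate 1 the cytokine (0.99), effector (0.71), interferon-stimulated (0.68) and negative regulator lists (0.52) were above all random lists. In replicate 3 immediate-early genes (0.80), mitochondrial mRNAs (0.66), cytokines (0.51), effectors (0.43), stress genes (0.32) and negative regulators (0.31) were above all random lists, and interferon-stimulated genes were below all of them (-0.40). Each shift in replicates 1 and 3 is taken against a mean that includes replicate 2. Replicate 3 against replicate 1 gave -0.04 for cytokines, -0.02 for effectors, 0.01 for negative regulators, 0.35 for immediate-early and -0.60 for interferon-stimulated genes. Each shift belongs to 1 library, and the RNA input differed between the 3 libraries.

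**Figure D3:**
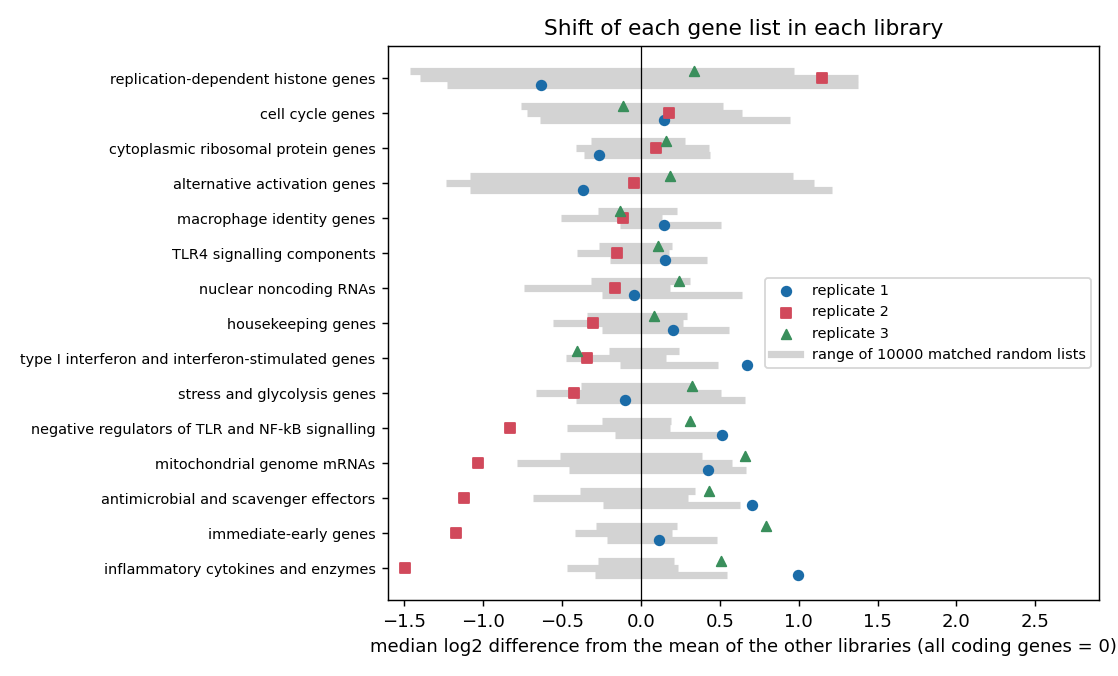
Median log2 difference of each list in 1 library from the mean of the others, relative to all protein-coding genes, for list members kept by the count filter. Grey bars span 10000 random lists matched on expression. The cytokine list in replicate 2 lies at -1.49, outside its bar.

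By annotated transcript class, small RNAs took 52.0 ± 1.73% of TPM, protein-coding transcripts 16.6 ± 0.884%, long noncoding and processed transcripts 15.5 ± 2.55%, retained-intron transcripts 12.3 ± 1.09% and pseudogenes 2.42 ± 0.824% (SD, n = 3 each). Mitochondrial transcripts took 0.0659 ± 0.0228%, transcripts typed as ribosomal RNA 0.00347 ± 0.00331% and other classes 1.15 ± 0.139%. These classes follow the type of each transcript, and the main transcript of CT010467.1, with 14062 TPM, is typed as a pseudogene and counts there, although its gene is typed as ribosomal RNA. In expected counts the shares were 1.03 ± 0.101% for small RNAs, 45.3 ± 1.38% for protein-coding, 33.7 ± 3.76% for long noncoding and processed, 16.6 ± 2.24% for retained-intron transcripts and 1.19 ± 0.234% for pseudogenes. Gm26917, typed as long intergenic noncoding, had a mean of 2.426e+06 expected counts. It is part of the ribosomal RNA locus, which took 10.5%, 20.8% and 18.2% of expected counts in replicates 1, 2 and 3. The long noncoding share therefore includes reads of that locus, and the share typed as ribosomal RNA does not measure ribosomal RNA. The second transcript table gave small RNAs 30.2 ± 1.27% of TPM.

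**Figure D4:**
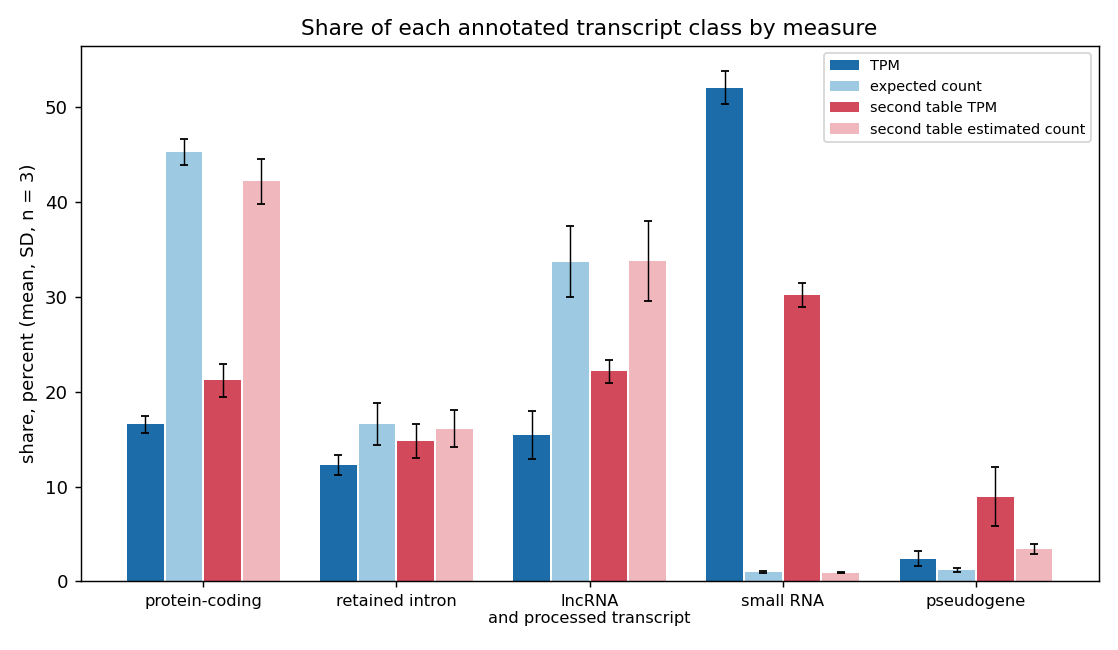
Share of 5 annotated transcript classes in percent, as bars of the mean with SD over 3 libraries, by TPM and by counts in both transcript tables. Small RNAs took 52.0% of TPM and 1.03% of expected counts in the first table.

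The gene table and the first transcript table summed per gene had no gene over 2-fold apart in any library. Against the second transcript table, Pearson's r across genes was 0.677, 0.675 and 0.675 in replicates 1, 2 and 3, and Spearman's rho 0.618, 0.620 and 0.612. On average 49.3 ± 0.821% of genes were over 2-fold apart, 15180 higher in the second table and 494 higher in the gene table. Among genes over 1 TPM in the gene table, r was 0.878, 0.859 and 0.870. Nos2 had 5.16 TPM in the gene table and 13.0 TPM in the second table, while Tnf had 484 and 493 TPM.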

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

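Among the tests in this part, the one on opposite-strand overlap was set before its result was seen, and the tests of gene length and GC content, macrophage share, RNA input, short RNAs and rescaled TPM were chosen after the results were seen.

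Reads of phiX, a control genome added to sequencing runs, were present outside the gene measurements, above the limit that a count of 0 allows. They made up 1.04% of expected counts in replicate 1, 0.425% in replicate 2 and 0.401% in replicate 3. The numbered rows that name no gene held 31, 23 and 33 counts in replicates 1, 2 and 3.

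Cytokine, immediate-early and negative regulator genes were lower in replicate 2, with a median shift of -1.17 log2 units over 61 genes. After trends on effective length and GC content were removed the shift was -1.28 (bootstrap SE 0.09), while other genes moved by a median of 0.14, which argues against these properties as the whole cause. A lower share of macrophages would lower macrophage identity genes too, and these were shifted by -0.11 (bootstrap SE 0.11). RNA input cannot be told apart from replicate, with 1 library per amount. The same genes differed by 0.10 (bootstrap SE 0.10) between replicates 3 and 1, which also had different inputs. That value does not speak to the lowest input, which only replicate 2 had. Lists outside these genes moved in replicate 2 as well. Mitochondrial mRNAs were shifted by -1.03 (8 of 8 lower) and 5 histone genes by 1.15 (percentile 99.9). A weaker or differently timed response in that culture may remain, but these values do not separate it from other differences of that library. No biological explanation was tested.

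Short RNAs took most of the TPM. Genes with an effective length under 100 bases had 53.4% of TPM and 1.08% of expected counts. TPM divides counts by effective length, so a gap in this direction is built in, and these shares do not decide whether the high TPM reflects abundance. No biological explanation was tested.

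The second transcript table put 19620 genes above 1 TPM, against 12220 in the gene table. Rescaling the gene table over genes of at least 100 bases gave 13774, so the TPM taken by short RNAs accounts for a minor part of the gap. The 7562 genes called only in the second table had a median of 0.333 expected counts in the gene table and 91.4 estimated counts in the second. Of these genes 17.0% overlapped a called gene on the opposite strand, against 9.44% of genes called in neither table, but 12.8% against 4.66% overlapped one on the same strand, so counting without strand may contribute and is not decided. No biological explanation was tested.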

How the results depend on the processing

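Of 521 alternatives over 65 results, 448 kept the direction and side of the threshold, or stayed within 1.5 times a count or 1 SD of a value. The rescaling over genes of at least 100 bases was chosen after seeing the data, and where no cause is named below the cause was not tested. No paired analysis was possible because the series has 1 group. Genes above 1 TPM were 12220, with 11708 to 11907 when a replicate was left out, 7384 with a floor of 5 TPM and 19620 in the second transcript table. By construction the higher floor left 2 alternative activation, 6 stress, 2 cell cycle, 0 dendritic, 0 erythroid and megakaryocyte and 0 histone genes, and the floor of 0.5 TPM gave 11 cell cycle, 2 dendritic and 6 histone genes. The rescaling over genes of at least 100 bases gave 11 cell cycle, 3 dendritic and 7 histone genes. The second transcript table called 2 lymphoid, 1 granulocyte, 3 dendritic and 1 stromal marker. TPM rescaled without mitochondrial and top noncoding genes gave 0 mitochondrial genes, which it removes, and 4 histone genes. A pseudocount of 1 gave 1 histone gene, as did each replicate left out (range 1 to 1). Of 1147 alternatives for named genes 1096 kept their call, 26 gained and 25 lost one. Against a floor of 5 TPM the called genes Clec10a (-0.12), Batf3 (-0.36), Pf4 (-0.61), Gp9 (-0.87), Hist1h2bc (-1.31), Nos2 (-0.060), Gm26759 (-0.11) and Gem (-0.24) fell below the floor in log2 level and lost their calls. The uncalled genes Itga2b (-1.78), Hist1h1c (-1.57), Il6 (-1.19), Lcn2 (-1.42), Ifnb1 (-2.11) and Fosb (-1.48) were below that floor too. Uncalled genes turned to the other side of the floor under other alternatives. With a floor of 0.5 TPM Clec9a (0.83), Zbtb46 (0.61) and Il12b (0.0083) were above it, and without mitochondrial and top noncoding genes Clec9a (0.56) and Zbtb46 (0.34). Rescaling over genes of at least 100 bases gave Ngp 0.051, Clec9a 0.99, Zbtb46 0.76 and Il12b 0.013. In the second transcript table Cd8a (1.31), Clec9a (0.32), Zbtb46 (0.86), Col1a1 (0.79) and Il12b (0.13) were above 1 TPM and Ifnb1 (-0.041) below. With a replicate left out, levels ranged from -0.16 to 0.077 for Clec9a, -1.67 to 0.0065 for Il12b, -0.21 to 0.32 for Ifnb1 and -0.55 to 1.54 for Fosb. Calls of Gm26759 without replicate 2 or 3, Gem without replicate 1 or 3, and Slc7a11, Srgn and Dnmt3l-ps1 without replicate 1 were among those lost. Against all protein-coding genes, which adds silent genes to the background, alternative activation genes reversed to 0.43, cell cycle genes to 1.81 and histone genes to 1.19, and lymphoid (-2.43), granulocyte (-2.63), dendritic (-1.46), erythroid (-2.06) and stromal markers (-2.24) lost their calls. With CPM, effectors (1.85), ribosomal protein (0.10) and mitochondrial genes (0.14) lost theirs and histone genes passed (-2.79), while cytokines against effectors turned to 0.055. In the second transcript table alternative activation (-1.65), dendritic (-2.43) and mitochondrial genes (1.74) lost theirs and cell cycle genes turned to 0.026. With a replicate left out, ranges were 1.17 to 2.32 for cytokines, 1.42 to 1.66 for ribosomal protein, 1.77 to 2.36 for mitochondrial, -2.50 to -1.94 for histone and -0.25 to 0.64 for stress genes, and -0.66 to 0.26 for cytokines against effectors. Cytokines against interferon-stimulated genes gave -0.97 over members with at least 10 counts, where cytokines against negative regulators turned to 0.49 and immediate-early genes against cytokines to -0.84. With no filter 6912, 6119 and 6592 genes were over 2-fold apart between replicates 1 and 2, 1 and 3, and 2 and 3, since genes of few counts then enter. The coefficient of variation was 0.173 to 0.251 with a replicate left out, and 0.134 from DESeq2 as the root of the median gene-wise dispersion. The mean r between gene table and second transcript table was 0.748 with a pseudocount of 1 and 0.869 among genes over 1 TPM, with 31.8% and 22.0% over 2-fold apart. In the second transcript table the TPM shares were 22.2% for long noncoding, 2.31% other, 21.2% protein-coding, 8.92% pseudogene, 0.336% for transcripts typed as ribosomal RNA, 14.8% retained-intron and 30.2% small RNA. In expected counts they were 33.7% long noncoding, 0.0422% mitochondrial, 2.14% other, 45.3% protein-coding, 1.19% pseudogene, 16.6% retained-intron and 1.03% small RNA. Depth limits genes near 0, where 3 counts equal 0.242, 0.164 and 0.165 CPM in replicates 1, 2 and 3.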

Other observations

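The test in this part was chosen after the data were seen. Reads of several inflammatory genes were assigned in part to transcripts annotated as retaining an intron. The share was 87.1 ± 4.79% for Cxcl1, 79.7 ± 5.15% for Cxcl2, 79.1 ± 3.40% for Cxcl10, 73.2 ± 0.751% for Ccl5 and 39.4 ± 6.75% for Il1b (SD, n = 3). Unspliced RNA can be assigned to such transcripts, so the share is not a measure of mature isoforms. The 6 cytokine and enzyme genes with such a transcript and at least 50 reads had a median of 76.2%, which was 48.1 percentage points above that of other coding genes (permutation p = 0.00133, adjusted p = 0.00665 over 10 lists). Ribosomal protein genes had 61.9%, which was 33.9 points above (20 genes, permutation p = 0.00028, adjusted p = 0.0028), with Rpl3 at 97.0 ± 2.00% and Rpl10 at 81.5 ± 3.24%. None of the other 8 lists passed, with macrophage identity genes at 15.7% and negative regulators at 27.4%. The random sets were not matched on expression or gene structure. They also took no account of small RNA genes inside other genes, such as Snord15b, which lies within the ribosomal protein gene Rps3 on the same strand. Whether reads of such small RNAs entered the shares was not tested. Single genes outside the cytokine and ribosomal protein lists, picked for their values, had shares as high. Examples were Fth1 (95.4%), Clec4e (92.9%), Dusp1 (92.7%) and Tnip3 (88.0%). In the second transcript table the medians were 74.9% for the cytokine and 54.4% for the ribosomal protein genes. Tnfaip3 had 68.7 ± 3.16%, Nfkbia 2.73 ± 0.305% and Mx1 3.14 ± 0.999%.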
